A study of Mus musculus with 9 samples.

How the data were processed

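The series measured gene expression in very small embryonic-like stem cells (VSEL), haematopoietic stem cells (HSC) and the ESC-D3 line of mouse embryonic stem cells, with 3 arrays for each of the 3 cell types. VSEL and HSC were sorted from the bone marrow of C57BL/6 mice aged 4 weeks, per the labels' protocols. Both gates took Sca-1-positive cells without lineage markers, and CD45 set them apart: VSEL lacked it and HSC carried it. ESC-D3 cells were grown on 0.1% gelatin with leukaemia inhibitory factor at 10 ng/ml, per the labels' protocols. Each library came from 20 sorted cells that were lysed without RNA purification, and the cDNA was made with a T7 primer, amplified by PCR, labelled with biotin by in vitro transcription and hybridised to an Affymetrix mouse expression array, per the labels' protocols. No label said whether the libraries of a group came from separate mice or cultures, so p-values measure only the spread between these libraries, which may be technical.

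The deposited values are log2 expression values per probe set, and the authors used RMA and Partek 6.5, per the submitters' processing notes. RMA corrects background, normalizes arrays by quantiles and summarises the probes of a set. The settings of these steps and the set of arrays normalized together are not given in the sources used here. The upper quartile of the log2 values was 6.63 to 6.69 on the VSEL arrays and 7.12 to 7.18 on the others, while the lower quartiles were 3.88 to 3.95 and 3.67 to 3.73. They were used as deposited, with no further normalization. No detection calls were used, and the number of arrays limits the precision.

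The table held 45101 probe sets, of which 64 were array controls and were left out of all tests. The platform annotation listed 35890 probe sets, 932 of them with several genes and 34958 with 1 gene, and 9211 were not listed. Symbols of 34741 of the 34945 one-gene probe sets that were not controls were updated through their gene identifiers in the RefSeq table of assembly GRCm38.p6, and 204 kept the annotation's symbol. No coordinates are given, because the build behind the annotation is not given in the sources used here. Each of the 18193 genes was read from its probe set with the highest mean, and 9010 genes had several probe sets. Probe sets of the same gene were called in opposite directions for 80 genes in VSEL against HSC, 83 in VSEL against ESC and 8 in HSC against ESC. Background was the lower quartile of all genes on each array, 4.49 to 4.80, because only 39 olfactory receptor genes were measured and the rule asked for 50. Differences against a group near that level can understate the true ratio. This background was 4.72 to 4.80 on the VSEL arrays and 4.49 to 4.55 on the others. For dim genes a value higher in VSEL can therefore also be overstated.

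VSEL arrays 2 and 3 differed far less than any other pair of a group (the report gives the values). After this was seen, they were averaged and counted as 1 library, called VSEL 2+3. The tests therefore rest on 8 libraries with 2 for VSEL. The design as written before the data were examined kept all 9 arrays separate, and its counts are given with the other alternatives.

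Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in a single fit over the 3 cell types, with 5 residual degrees of freedom and an estimated prior of 1.37. This fit assumes that a gene has the same spread in all 3 cell types, and most of its estimate comes from HSC and ESC. The VSEL libraries correlated at only 0.776, against 0.922 to 0.951 within HSC and ESC. SEs and p-values of comparisons with VSEL can therefore be too small. P-values were adjusted by Benjamini-Hochberg over all genes within a contrast, and a gene was called at an adjusted p of 0.05. A moderated F test covered the 3 cell types together. The 24 gene lists were fixed before the data were examined: pluripotency, HSC and progenitor, pan-leukocyte, erythroid, B lineage, T and NK, granulocyte and monocyte, megakaryocyte and platelet, mesenchymal and osteoblast, endothelial, DNA replication, mitosis, cell cycle inhibitors, Polycomb, DNA methylation, imprinted, germ cell, developmental regulators, ribosomal proteins, oxidative phosphorylation, glycolysis, immediate early and stress, MHC class I and interferon, and p53 targets. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. With an estimated correlation camera also takes its p-values from the 5 residual degrees of freedom of the fit, which raises them. A call lost there therefore need not come from correlation between genes. Among lists that lost a call, the estimate was below 0.01 for MHC class I and interferon (-0.0621), cell cycle inhibitor (-0.0469), DNA methylation (-0.0107) and mesenchymal genes (0.00371). Members were counted at the adjusted p over all genes and adjusted over the list alone. Lists among the genes that set VSEL apart from both other cell types were tested with a one-sided Fisher's exact test against all genes, adjusted over lists and directions, a test added after seeing the data. Some list members were not analysed here.

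The genes named were set by a rule written before the data were examined. It took, per contrast, the 6 largest called differences in each direction whose values did not overlap between the groups and whose higher mean was above background, up to 3 members of each list with the smallest p, and the genes Ptprc, Kit, Pou5f1, Nanog, Sox2, Ezh2, Igf2, Cdkn1c and Mki67 whatever their values. The text prints a part of these. It favours genes whose call did not depend on a single library, and of 222 called values under the rule 187 kept their call when any library was left out. Genes outside the rule are named as such.

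Alternatives covered the choice and filtering of probe sets, quantile, cyclic loess and ribosomal protein scaling, the fit on 2 groups, the trend and robust settings of eBayes, array weights, a replicate block, the difference between the 3' and 5' ends of the Gapdh and beta-actin controls as a covariate, each array left out, and a 2-fold minimum. After seeing the data, the replicate block was redefined on the 9 arrays, VSEL 1 as the only VSEL library was added, and the 9 separate arrays, the design as first written, became an alternative. The scripts were tested on simulated data with 200 changed genes among 18193. In VSEL against HSC the fit recovered 0 of these at a log2 change of 1, 93 at 2 and 145 at 4. In VSEL against ESC it recovered 0, 95 and 148, and in HSC against ESC 15, 97 and 153. With the pluripotency list moved by 1 or 2 log2 units in VSEL against HSC, the list was called each time and no other list was. These simulations drew each gene independently, whereas the estimated correlation reached 0.643 in the granulocyte and monocyte list. They therefore do not show how often lists of correlated genes are called without a shift.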

Results

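Expression was measured on 9 arrays, 3 each for VSEL, HSC and ESC-D3 (called ESC below). VSEL are small cells described in bone marrow and proposed to share features with embryonic stem cells. HSC here are cells of the bone marrow gate that carries CD45. ESC-D3 is a pluripotent line from a mouse blastocyst. Values are log2 RMA values, each group is given as mean ± SD over its libraries, and n is 2 for VSEL, 3 for HSC and 3 for ESC throughout.

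VSEL arrays 2 and 3 correlated at r = 0.989 across probe sets, and the SD of their difference over bright probe sets (pair mean above 9) was 0.199. Every other pair within a group had r between 0.831 and 0.957 and an SD of at least 0.491. A single probe set differed by more than 4-fold between VSEL 2 and 3, against 1565 to 4232 in the other pairs of a group. Arrays 2 and 3 were therefore counted as 1 sample. The hybridisation controls, which are added in a fixed amount, averaged 11.31, 11.73 and 11.36 on VSEL arrays 1, 2 and 3, 10.51 ± 0.18 on the HSC arrays and 10.44 ± 0.095 on the ESC arrays. The mean 3' minus 5' difference of the Gapdh and beta-actin controls was 0.709 to 1.07 in VSEL, 0.734 to 0.962 in HSC and 0.34 to 0.446 in ESC.

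The first question was how near VSEL lie to HSC or to ESC over the whole transcriptome. Across genes, the 2 VSEL libraries correlated at r = 0.776 with each other, while HSC libraries reached 0.922 to 0.944 and ESC libraries 0.945 to 0.951. VSEL correlated with HSC at 0.752 to 0.782 and with ESC at 0.779 to 0.808, and HSC with ESC at 0.74 to 0.775. The VSEL libraries were thus about as far from each other as from the other cell types. These are correlations across genes, which are not independent replicates. The values of VSEL lay wholly above or below those of HSC for 55.2% of genes and those of ESC for 55.6%, where chance gives 20%. The share was 38% for HSC against ESC, where chance gives 10%. VSEL lay above HSC for 6886 genes and below for 3148, and above ESC for 6007 and below for 4117. HSC lay above ESC for 3006 and below for 3906. The lower quartile of genes was 4.72 to 4.80 on VSEL arrays and 4.49 to 4.55 on the others. A higher floor on the VSEL arrays thus cannot be told apart from part of these shares.

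**Figure D1:**
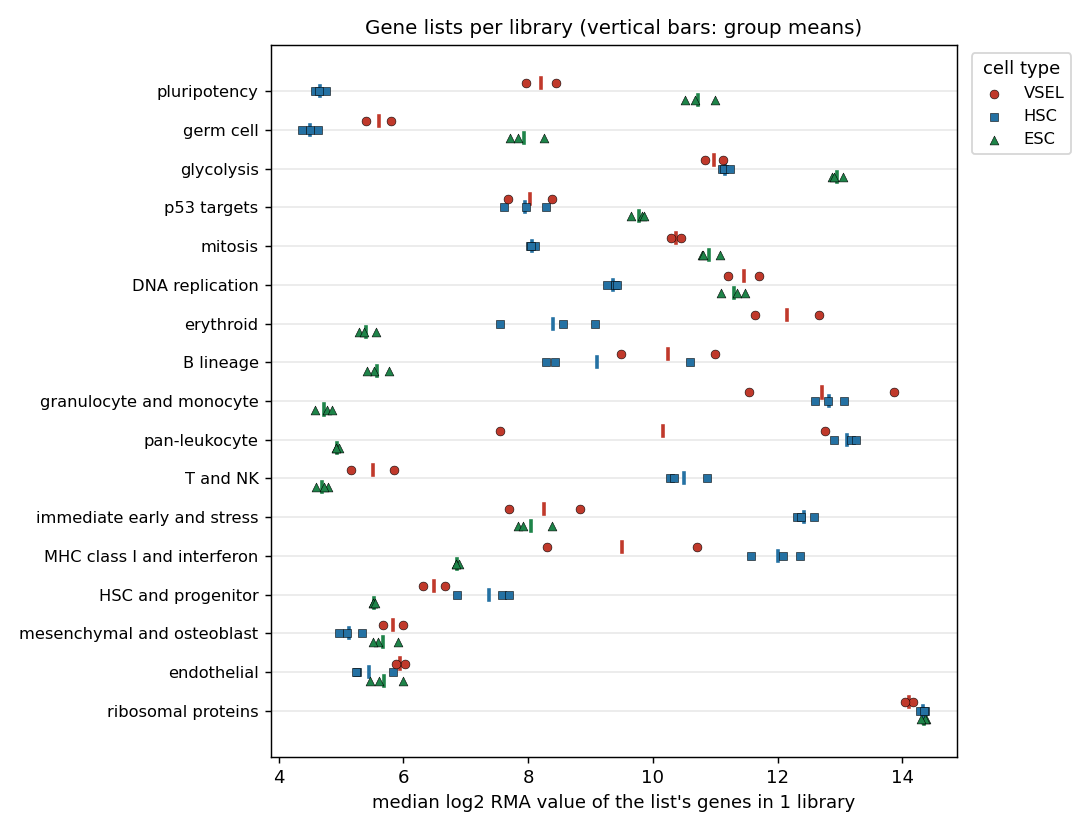
Median log2 RMA value of the genes of 17 lists in each of the 8 libraries, with a point per library and a bar at the mean of each cell type. Pluripotency genes lay at 8.21 in VSEL, between 4.66 in HSC and 10.73 in ESC, while the pan-leukocyte medians of the VSEL libraries were 7.55 and 12.76.

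VSEL against HSC asks what sets the CD45-negative gate apart from the CD45-positive gate of the same marrow. Pluripotency and cell cycle genes were higher in VSEL, and T and NK cell, immediate early and interferon genes were lower. Zfp42, a transcription factor of undifferentiated embryonic stem cells, lay at 10.48 ± 0.028 in VSEL and 2.98 ± 0.097 in HSC, a log2 difference of 7.50 (SE 0.13; limma with Benjamini-Hochberg, adjusted p = 5.12e-06). Ptprc, which encodes the CD45 antigen of the gate, lay at 3.42 ± 0.24 in VSEL and 13.54 ± 0.14 in HSC, so it fell by 10.12 (SE 0.17, adjusted p = 5.12e-06). Since the sort used this antigen, the Ptprc difference is not independent of the gate, and its cause was not tested. Every called gene named in this report had all its values in the one group above all those in the other.

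Of the 27 measured pluripotency genes, 19 were higher in VSEL than in HSC, 1 was lower and 7 were not called (camera adjusted p = 6.57e-13; 21 higher and 1 lower adjusted over the list alone). Dppa5a was 199-fold higher, Pou5f1 (Oct4, a core factor of pluripotency) 89.9-fold, Tdgf1 61.5-fold, Nanog 41.2-fold and Sox2 33.2-fold. The log2 difference of Pou5f1 was 6.49 (SE 0.27, adjusted p = 5.97e-05) and that of Nanog 5.36 (SE 0.17, adjusted p = 1.82e-05). In the germ cell list 4 of 14 were higher and none lower, and the list was not called (adjusted p = 0.128). The DNA methylation list was not called either (adjusted p = 0.0768), with 1 of 8 members higher: Dnmt3l, a cofactor of the de novo methyltransferases, by 2.81 (SE 0.18, adjusted p = 0.000315). Among developmental regulators 10 of 33 were higher and none lower (adjusted p = 1.58e-05), and this call was lost with an estimated correlation (adjusted p = 0.139). Gata6, an endoderm factor, led them at 7.93 ± 0.20 against 5.27 ± 0.030 (adjusted p = 0.000355). Mesenchymal genes were higher for 5 of 18 and lower for none (adjusted p = 0.00425, but 0.0778 as adjusted p with an estimated correlation). The list was also not called with VSEL 1 as the only VSEL library. The medians of the developmental and mesenchymal lists were 5.845 and 5.835 in VSEL and 5.181 and 5.131 in HSC. The 95th percentile of the olfactory receptor genes was 6.25 to 6.45 on VSEL arrays and 5.57 to 5.85 on HSC arrays. These list medians lay below it, so a higher floor on the VSEL arrays cannot be told apart from the list shifts. Pdgfra was 6.73-fold higher (adjusted p = 0.00854) and Sparc, a matrix protein gene, 41.2-fold (adjusted p = 0.0137). Many of these genes were higher still in ESC. Of the 19 pluripotency genes higher in VSEL than in HSC, 16 belong to 133 genes chosen as high in ESC over HSC. Most of the 133 lay in VSEL at a common offset below ESC, as given with VSEL against ESC. All 19 pluripotency genes had a higher mean in ESC than in VSEL, a count of means without a test. So did all 4 germ cell genes, Dnmt3l, 3 of the 10 developmental regulators and 3 of the 5 mesenchymal genes. Among the 133 genes were Dnmt3l, Gata6 and Sparc, whose offsets from ESC were -2.05, -2.15 and -2.92 in VSEL 1 and -2.09, -2.44 and -2.55 in VSEL 2+3. Pdgfra, outside the 133, lay at 6.60 ± 0.36 in VSEL and 8.70 ± 0.65 in ESC.

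Cell cycle genes were higher in VSEL. In the DNA replication list 12 of 27 were higher and none lower (adjusted p = 2.43e-06; 16 adjusted over the list alone), with Prim1, a subunit of DNA primase, 9.16-fold higher and Tk1 6.78-fold higher. In the mitosis list 18 of 27 were higher and none lower (adjusted p = 2.83e-07; 19 adjusted over the list alone). Bub1, a spindle checkpoint kinase gene, lay at 10.73 ± 0.39 in VSEL and 5.76 ± 0.59 in HSC (adjusted p = 0.00128), and Mki67 at 12.03 ± 0.49 and 8.94 ± 0.81 (adjusted p = 0.0103). Of the genes higher than in HSC, 3 of 12 in the DNA replication list and 10 of 18 in the mitosis list had a higher mean in ESC than in VSEL. Ezh2, the methyltransferase of Polycomb complex PRC2, was 8.62-fold higher (adjusted p = 0.00141), while Eed of the same complex was 2.50-fold lower (adjusted p = 0.00796), a call that ended after another quantile normalization. The other probe set of Eed had the opposite sign in every contrast and was not called. The Polycomb list was not called (1 higher, 3 lower of 21; adjusted p = 0.195). Atad5, a gene of DNA replication outside the lists and named by its size, was 159-fold higher (adjusted p = 7.85e-06).

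T and NK cell genes were lower in VSEL for 8 of 12 and higher for none (adjusted p = 2.76e-10; 10 adjusted over the list alone). Cd3g, part of the T cell receptor complex, lay at 4.28 ± 0.14 in VSEL and 12.82 ± 0.24 in HSC, and Klrd1, an NK receptor gene, at 3.51 ± 0.14 and 11.22 ± 0.26 (adjusted p = 7.85e-06 and 7.41e-06). The median of this list was 10.49 ± 0.32 in HSC. Immediate early genes were lower for 12 of 16 and higher for none (adjusted p = 8.35e-12). Fosb was 732-fold lower and Fos 116-fold lower (adjusted p = 4.13e-05 and 0.000151). Of the 11 MHC class I and interferon genes, 4 were lower and none higher (adjusted p = 9.97e-06), and Irf1, an interferon response factor gene, was 36.5-fold lower. Pan-leukocyte genes were lower for 4 of 16 (adjusted p = 9.01e-06), a call lost with an estimated correlation (adjusted p = 0.153). Cd48 was 115-fold lower and Itgb2, an integrin gene of leukocytes, 105-fold lower. The median of the pan-leukocyte list was 7.55 in VSEL 1 and 12.76 in VSEL 2+3.

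Both gates excluded cells with lineage markers, and genes of several blood lineages were measured in both. Erythroid genes were higher in VSEL for 9 of 15 and lower for none (adjusted p = 9.16e-06), a call lost with an estimated correlation (adjusted p = 0.159). Alas2, the first enzyme of haem synthesis in red cell precursors, was 22.8-fold higher and the membrane protein gene Slc4a1 24.7-fold higher (adjusted p = 0.0063 and 0.009). The erythroid median was 11.63 and 12.66 in the VSEL libraries and 7.55 to 9.07 in HSC. The B lineage list was not called (4 higher of 13; adjusted p = 0.264). Its members Rag1, which cuts antigen receptor genes in lymphocyte precursors, and Vpreb3 were higher by log2 differences of 7.07 and 3.94 (adjusted p = 0.000502 and 0.00377). The granulocyte and monocyte list was not called (2 lower of 18; adjusted p = 0.31), with medians of 12.71 ± 1.65 in VSEL and 12.82 ± 0.23 in HSC. The HSC and progenitor list was not called (4 higher, 3 lower of 21; adjusted p = 0.559), although Gfi1 and Fli1, transcription factor genes of blood cells, were 64.0-fold and 37.3-fold lower. The other probe set of Fli1 had the opposite sign and was not called. Kit was 7.01 ± 0.49 in VSEL and 8.34 ± 0.70 in HSC and was not called (adjusted p = 0.109).

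Adjusted over the list alone, the counts in VSEL against HSC became 14 higher for erythroid genes, 18 for developmental regulators, 6 for mesenchymal and 5 for germ cell genes, and 14 lower for immediate early genes. They became 4 higher and 4 lower for HSC and progenitor genes, 2 higher and 3 lower for megakaryocyte genes, 3 higher and 3 lower for p53 targets, 1 lower for granulocyte and monocyte genes and 0 for ribosomal proteins. Apart from the lists given above with both counts, the others kept theirs.

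The ribosomal protein list was lower (2 of 25 members; adjusted p = 0.00373), but its adjusted p was 0.162 with an estimated correlation, and it was not called after cyclic loess, among genes above the median, or, by construction, when arrays were centred on it. Megakaryocyte (1 higher and 3 lower of 12; adjusted p = 0.183), endothelial (0 of 16; 0.412), cell cycle inhibitor (2 lower of 14; 0.183), imprinted (1 higher and 1 lower of 25; 0.183), oxidative phosphorylation (3 lower of 28; 0.412), glycolysis (2 lower of 13; 0.617) and p53 target genes (3 higher and 2 lower of 13; 0.965) were not called by camera at these adjusted p. Plek, a gene of platelets and leukocytes, was 55.7-fold lower (adjusted p = 0.000816) and Cdkn1a, the cell cycle inhibitor p21, 4.02-fold lower (adjusted p = 0.0099). Igf2 was 7.89 ± 0.023 in VSEL and 6.89 ± 0.66 in HSC (adjusted p = 0.131), and Cdkn1c 6.28 ± 0.57 and 6.35 ± 1.08 (adjusted p = 0.951).

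In all, 3129 of 18193 genes differed between VSEL and HSC, 1458 higher and 1671 lower in VSEL (46.6% higher), and 2302 of them by at least 2-fold, 671 higher and 1631 lower. The share higher was 61.8% after another quantile normalization and 80% with arrays centred on ribosomal proteins. That centring moved the median of all genes by 0.43. The share was 30% among genes above the median, 32% in a fit on these groups alone and 30.7% with array weights. Without HSC 1, 2 or 3 it was 36.4%, 35.2% or 33.8%, with 712, 765 or 681 genes higher and 1242, 1410 or 1334 lower. The balance of directions thus rests on the scaling, the genes tested, the fit and single libraries. The count was 7692 with that centring, 1998 among genes above the median, 1954 without HSC 1, 2015 without HSC 3, 1586 in a fit on these groups alone, which ended the Mki67 and Sparc calls, 1249 with array weights and 4757 with the 9 arrays kept separate. Leaving out probe sets that can match several transcripts ended the Ptprc call, since the remaining probe set gave a log2 difference of -0.53 (adjusted p = 0.534).

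VSEL against ESC asks how far VSEL share the expression state of a pluripotent line. Pluripotency genes were lower in VSEL than in ESC (20 of 27). Genes of several blood lineages were higher, but each of their list calls was lost with an estimated correlation (adjusted p of 0.0951 to 0.229). Zfp42 lay at 10.48 ± 0.028 in VSEL and 13.10 ± 0.057 in ESC, so it fell by 2.62 (SE 0.13, adjusted p = 0.000414 from limma), Nanog fell by 2.90 (SE 0.17, adjusted p = 0.000608) and Pou5f1 fell by 3.01 (SE 0.27, adjusted p = 0.00167). S100a9, a calcium-binding protein gene of neutrophils, lay at 14.25 ± 1.17 in VSEL and 3.79 ± 0.12 in ESC, a log2 difference of 10.47 (SE 0.46, adjusted p = 0.000283).

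Of the 27 pluripotency genes 20 were lower in VSEL and none higher (camera adjusted p = 8.69e-17; 21 adjusted over the list alone). Sox2 fell by 2.77 and Tdgf1 fell by 2.70 on the log2 scale (adjusted p = 0.0022 and 0.000455). Germ cell genes were lower for 7 of 14 (adjusted p = 0.000212, and 0.0497 as adjusted p with an estimated correlation), among them Mael by 10.1-fold and Kit by 8.18-fold. The germ cell list was not called among genes above the median. Of the DNA methylation genes 2 of 8 were lower (adjusted p = 0.0314, but 0.117 as adjusted p with an estimated correlation), namely Dnmt3l, 4.19-fold, and Dnmt3b, 6.35-fold. The list lost its call in 9 of 25 settings, which also include the replicate block (adjusted p = 0.0507), the 3' to 5' covariate (0.0858), cyclic loess (0.115), the filters on the median (0.124), on background (0.08) and on probe sets that can match several transcripts (0.174), and leaving out VSEL 1 (0.271) or ESC 1 (0.0502). Developmental regulators were not called as a list (2 higher, 3 lower of 33; adjusted p = 0.164), while Gata6 was 4.90-fold, Gata4 6.23-fold and Otx2 8.57-fold lower. Glycolysis genes were lower for 10 of 13 and higher for 1 (adjusted p = 7.81e-07), with the glucose transporter gene Slc2a1 6.08-fold and the enzyme gene Tpi1 5.83-fold lower. Targets of p53 were lower for 7 of 13 and higher for none (adjusted p = 6.32e-06), among them Ccng1 by 7.54-fold and Eda2r by 5.34-fold.

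The offset from ESC was measured over genes called specific to ESC, a name that rests on the comparison with HSC alone. A rule set after the data were examined, but without VSEL values, took 133 genes whose lowest ESC value was more than 3 log2 units above the highest HSC value and whose ESC mean was above 10. Their median offset from ESC was -2.57 in VSEL 1 and -2.58 in VSEL 2+3, which on the linear scale is 16.8% of the ESC level in each. In VSEL 1 88% of the genes and in VSEL 2+3 91.7% lay within 1 log2 unit of that median. The set also holds cell cycle genes such as Bub1, Gins1 and Kif20a. Some members lay above ESC, such as Nup133 by 0.18 in VSEL 1 and 0.45 in VSEL 2+3. The 16 genes of the pluripotency list had a median offset of -2.78 in the mean of both libraries and the other 117 genes -2.53. Over 300 genes specific to HSC, chosen in the same way, only 19% and 10.3% lay within 1 log2 unit of the median offset from HSC, which was -3.96 in VSEL 1 and -2.85 in VSEL 2+3.

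**Figure D2:**
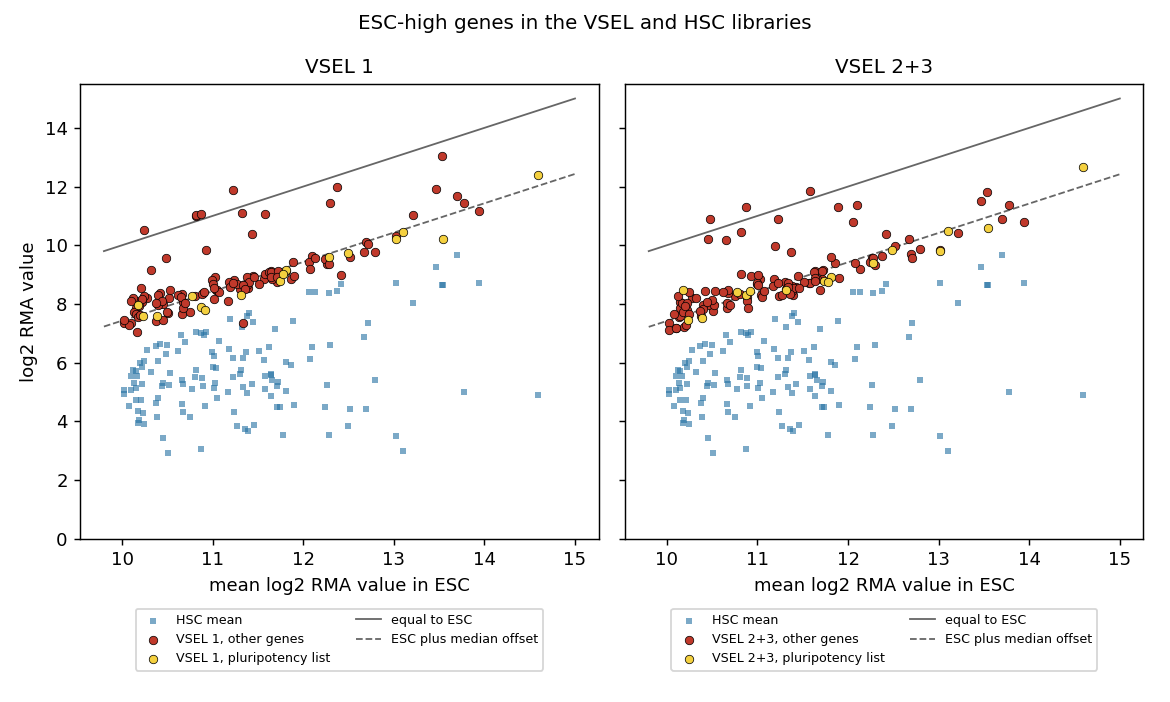
Log2 RMA value of 133 genes specific to ESC, with the ESC mean on the x axis and VSEL 1, VSEL 2+3 and the HSC mean on the y axis. The solid line marks equality and the dashed line the ESC mean plus the median offset, and both VSEL libraries follow the dashed line at -2.57 and -2.58.

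Blood cell lists other than the megakaryocyte list were called higher in VSEL than in ESC, and every one of these calls was lost with an estimated correlation. Granulocyte and monocyte genes were higher for 14 of 18 and lower for none (adjusted p = 3.64e-14; adjusted p = 0.117 with an estimated correlation), with Lcn2 1200-fold and Ngp 725-fold higher, both neutrophil granule genes. Erythroid genes were higher for 11 of 15 (adjusted p = 6.41e-09; adjusted p = 0.0951 with an estimated correlation), with Alas2 253-fold and Car1 122-fold higher. B lineage genes were higher for 8 of 13 (adjusted p = 5.59e-06; adjusted p = 0.0951 with an estimated correlation), with Rag1 144-fold and Vpreb3 135-fold higher. Pan-leukocyte genes were higher for 7 of 16 (adjusted p = 3.39e-07; adjusted p = 0.0988 with an estimated correlation), with the GTPase gene Rac2 198-fold higher. HSC and progenitor genes were higher for 5 and lower for 1 of 21 (adjusted p = 0.0147; adjusted p = 0.111 with an estimated correlation), with log2 differences of 6.04 for Lyl1 and 4.64 for Lmo2. MHC class I and interferon genes were higher for 4 and lower for 1 of 11 (adjusted p = 0.00148; adjusted p = 0.0752 with an estimated correlation), and Psmb8, an immunoproteasome subunit gene, lay at 12.13 ± 0.14 against 5.76 ± 0.24. This list was not called without the probe sets that can match several transcripts. T and NK genes were called as a list (1 higher of 12; adjusted p = 0.0314), but not with an estimated correlation (adjusted p = 0.229), with arrays centred on ribosomal proteins, without ESC 3, or with VSEL 1 as the only VSEL library. Ptprc was 3.42 ± 0.24 in VSEL and 3.03 ± 0.12 in ESC (adjusted p = 0.162).

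Cell cycle lists showed no call between VSEL and ESC. DNA replication had 3 genes higher and 1 lower of 27 (adjusted p = 0.861) and mitosis 2 higher and 5 lower of 27 (adjusted p = 0.0748). Ccne2 was 34.0-fold higher (adjusted p = 0.0051), Ezh2 3.58-fold higher (adjusted p = 0.0105) and Mad2l1 5.77-fold lower (adjusted p = 0.00286). Eed was 8.14-fold lower (adjusted p = 0.000831), and the Polycomb list was not called (2 higher, 3 lower of 21; adjusted p = 0.257). Cdkn2d, an inhibitor of cyclin-dependent kinases, and the antiproliferative gene Btg2 were 9.36-fold and 10.8-fold higher, in a cell cycle inhibitor list that was not called (4 higher, 1 lower of 14; adjusted p = 0.257). Oxidative phosphorylation genes were lower for 5 of 28 and higher for 1 (adjusted p = 0.000856; adjusted p = 0.0772 with an estimated correlation), with Ndufa9 7.36-fold lower. Ribosomal protein genes were lower for 3 of 25 and higher for 1 (adjusted p = 0.0136; adjusted p = 0.202 with an estimated correlation). Neither of these lists was called after cyclic loess, among genes above the median or with the 3' to 5' covariate, nor the ribosomal protein list among genes above background, with arrays centred on it or with VSEL 1 as the only VSEL library. Megakaryocyte (1 higher of 12; adjusted p = 0.24), mesenchymal (1 lower of 18; 0.861), endothelial (0 of 16; 0.968), imprinted (2 higher and 3 lower of 25; 0.618) and immediate early genes (3 higher and 2 lower of 16; 0.64) were not called by camera. Zfp36, which promotes decay of cytokine mRNAs, was 42.6-fold higher (adjusted p = 0.00232). Named by size outside the lists, C9orf72 was 11.9-fold, Atp6v1c1 10.2-fold and Gask1b 10.1-fold lower. The other probe set of Gask1b had the opposite sign and was not called.

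Adjusted over the list alone, the counts in VSEL against ESC became 7 higher for HSC and progenitor, 8 for pan-leukocyte, 13 for erythroid and 9 for B lineage genes, 0 for T and NK and for megakaryocyte genes, and 5 higher and 3 lower for developmental regulators. They became 4 higher and 2 lower for DNA replication, 1 higher and 3 lower for DNA methylation, 1 higher and 6 lower for oxidative phosphorylation, 1 higher and 11 lower for glycolysis, 3 higher and 3 lower for immediate early genes, 5 higher and 1 lower for MHC class I and interferon genes, and 9 lower for p53 targets. Apart from pluripotency, given above, the other lists kept their counts.

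In all, 3075 genes differed between VSEL and ESC, 1161 higher and 1914 lower in VSEL (37.8% higher), and 2391 by at least 2-fold, 528 higher and 1863 lower. Without ESC 1, 2 or 3, 484, 452 or 538 genes were higher and 1331, 1257 or 1397 lower. The share higher was 57% after another quantile normalization, 52.3% after cyclic loess and 69.3% with arrays centred on ribosomal proteins, which moved the median of all genes by 0.36, but 22.2% among genes above the median and 25.1% in a fit on these groups alone. The count was 5545 with that centring, 1815 without ESC 1, 1709 without ESC 2, 1935 without ESC 3, 1441 with array weights, 4719 with the 9 arrays separate, and 92 with the 3' to 5' control difference as a covariate, which itself differs between VSEL and ESC. Of the genes named here, S100a9, Lcn2, Ngp, Zfp42, Tdgf1, Rac2, Cdkn2d and Psmb8 were still called with that covariate and the others were not.

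HSC against ESC sets the marrow cells with CD45 against the pluripotent line and gives the scale for both other comparisons. Pan-leukocyte and T and NK cell genes were higher in HSC, and pluripotency and cell cycle genes were higher in ESC. Ptprc lay at 13.54 ± 0.14 in HSC and 3.03 ± 0.12 in ESC, a log2 difference of 10.51 (SE 0.15, adjusted p = 1.09e-06 from limma). Zfp42 fell by 10.12 (SE 0.12, adjusted p = 9.02e-07) and Dppa5a fell by 9.69 (SE 0.14, adjusted p = 1.09e-06).

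Of the 27 pluripotency genes 23 were lower in HSC and 1 was higher (adjusted p = 7.32e-24), with Pou5f1 725-fold, Nanog 307-fold and Sox2 226-fold lower. DNA replication genes were lower for 15 of 27 (adjusted p = 2.86e-08) and mitosis genes for 20 of 27 (adjusted p = 1.73e-13), with none higher in either list. Rrm2 was 7.31-fold and Bub1 33.4-fold lower, while Mki67 was 8.94 ± 0.81 in HSC and 10.01 ± 0.29 in ESC and was not called (adjusted p = 0.174). DNA methylation genes were lower for 5 of 8 (adjusted p = 0.000623), germ cell genes for 8 of 14 (adjusted p = 9.99e-06), glycolysis genes for 11 of 13 with 1 higher (adjusted p = 8.82e-07) and p53 targets for 6 of 13 (adjusted p = 0.000419). Dnmt3l was 29.4-fold, Tfap2c 14.6-fold, Slc2a1 7.24-fold and Phlda3 18.2-fold lower. Stmn2, a microtubule regulator gene named by its size, was 433-fold lower. Igf2 was 4.09-fold lower (adjusted p = 0.0111), and Cdkn1c was 6.35 ± 1.08 in HSC and 7.49 ± 0.81 in ESC (adjusted p = 0.337).

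All 16 pan-leukocyte genes (adjusted p = 2.96e-17) and all 12 T and NK genes (adjusted p = 3e-14) were higher in HSC. Cd3g was 471-fold and Klrd1 238-fold higher. Immediate early genes were higher for 14 of 16 (adjusted p = 1.91e-14), MHC class I and interferon genes for 10 of 11 (adjusted p = 5.4e-12), and HSC and progenitor genes for 8 of 21 with 2 lower (adjusted p = 0.000501). Fosb was 728-fold, Psmb8 168-fold and Gfi1 64.0-fold higher. Granulocyte and monocyte genes were higher for 16 of 18 (camera adjusted p = 4.11e-21, and adjusted p = 0.0531 with an estimated correlation), with S100a9 at 14.57 ± 0.24 in HSC. The estimated correlation of a list came from the residuals of the whole fit, VSEL included, and was the same in every contrast. For this list it was 0.643, and the SD of the list median was 1.65 in VSEL, 0.232 in HSC and 0.142 in ESC. B lineage genes were higher for 6 of 13 (adjusted p = 1.17e-05; adjusted p = 0.0579 with an estimated correlation), erythroid genes for 5 of 15 (adjusted p = 0.000787; adjusted p = 0.18 with an estimated correlation), megakaryocyte genes for 3 of 12 (adjusted p = 0.00839; adjusted p = 0.138 with an estimated correlation) and cell cycle inhibitors for 4 of 14 (adjusted p = 0.00828; adjusted p = 0.056 with an estimated correlation). Vpreb3 was 8.80-fold, Car1 19.8-fold, Plek 72.5-fold and Btg1 38.8-fold higher. Mesenchymal genes were lower for 5 of 18 (adjusted p = 0.0191; adjusted p = 0.0743 with an estimated correlation), developmental regulators for 5 of 33 (adjusted p = 0.00839; adjusted p = 0.2 with an estimated correlation) and oxidative phosphorylation genes for 7 of 28 (adjusted p = 0.0042; adjusted p = 0.0579 with an estimated correlation). The last was not called after cyclic loess. With the 3' to 5' covariate the erythroid, megakaryocyte, mesenchymal and oxidative phosphorylation lists were not called, nor was the megakaryocyte list among genes above the median. Sparc was 274-fold, Gata6 30.9-fold and Cyc1 3.20-fold lower. Endothelial (1 lower of 16; adjusted p = 0.331), Polycomb (2 higher and 4 lower of 21; 0.798), imprinted (1 higher and 6 lower of 25; 0.0694) and ribosomal protein genes (1 higher of 25; 0.798) were not called by camera.

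Adjusted over the list alone, the counts in HSC against ESC became 24 lower for pluripotency, 20 for DNA replication, 25 for mitosis, 10 for germ cell, 8 for oxidative phosphorylation and 6 for mesenchymal genes. They became 17 higher for granulocyte and monocyte, 15 for immediate early, 9 for HSC and progenitor, 8 for B lineage, 4 for megakaryocyte and 0 for ribosomal protein genes, and the other counts stayed as given.

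In all, 3078 genes differed between HSC and ESC, 1271 higher and 1807 lower in HSC, and 2930 by at least 2-fold. With the 3' to 5' control difference as a covariate, which is higher in HSC than in ESC, 845 genes were called, and the calls of Car1, Vpreb3, Sparc, Btg1, Cyc1 and Igf2 ended. Leaving out probe sets that can match several transcripts ended the Ptprc call here too, at a log2 difference of 1.04 (adjusted p = 0.276).

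Genes that set VSEL apart from both other cell types were those called in both comparisons with the same sign. Of the 15 erythroid genes 8 were higher in VSEL than in both (one-sided Fisher's exact test against all genes, adjusted p = 1.93e-07 over 48 tests), and of the 13 B lineage genes 4 (adjusted p = 0.0121). These tests were chosen after the data were seen and treat genes as independent. With the 3' to 5' covariate neither list had such a gene, and the B lineage call also ended after another quantile normalization (adjusted p = 0.134), with the ribosomal protein centring (0.601), without probe sets that can match several transcripts (0.11), in a fit on 2 groups (0.0507) and with the 9 arrays separate (0.163). HSC and progenitor (4 of 21; adjusted p = 0.0557), DNA replication (3 of 27; 0.587) and mitosis genes (2 of 27; 1) were not called as lists, and no other list was in either direction (adjusted p of at least 0.71). After cyclic loess the HSC and progenitor (adjusted p = 0.041) and DNA replication lists (0.0003) were called, as was the first among genes above the median (0.0164) and with the replicate block (0.0495) and the second without HSC 2 (0.00909). Ezh2 lay at 11.94 ± 0.34 in VSEL, 8.83 ± 0.37 in HSC and 10.10 ± 0.28 in ESC. Ermap, an erythroid membrane protein gene, lay at 12.61 ± 0.86, 8.97 ± 0.53 and 5.70 ± 0.34, and Vpreb3 at 14.23 and 12.80 in the VSEL libraries, 9.58 ± 0.38 in HSC and 6.44 ± 0.41 in ESC. Rag1 lay at 10.04 ± 1.35 in VSEL against 2.98 ± 0.018 and 2.88 ± 0.20. The oxidative phosphorylation genes Ndufa9 and Sdhb and the Polycomb gene Eed were lower than in both, with Eed at 7.94 ± 0.26 against 9.26 ± 0.13 and 10.96 ± 0.20. The other probe set of Eed had the opposite sign in both comparisons and was not called.

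There were 559 genes higher and 740 lower in VSEL than in both, 1299 together. Independent lists of the same sizes would share 93 and 176. At an unadjusted p under 0.05 in both comparisons, 3516 genes moved the same way, where 20 simulations without any effect but with the shared VSEL libraries gave a mean of 312. The 2 VSEL libraries are too few to divide between the comparisons, so part of the excess may come from sharing them. The share higher was 43%, and it was 74.5% after another quantile normalization, 65.6% after cyclic loess and 84.8% with arrays centred on ribosomal proteins, but 17.9% among genes above the median, 30.4% among genes above background, 22.3% in fits on 2 groups and 25.5% with array weights. At least 2-fold from both were 167 genes higher and 703 lower. The count was 35 with the 3' to 5' covariate, 380 with array weights, 435 in fits on 2 groups, 847 after cyclic loess and 3775 with the ribosomal protein centring. It was 807 without HSC 1, 814 without HSC 3, 659 without ESC 1, 652 without ESC 2 and 723 without ESC 3, and 2254 with the 9 arrays separate. Without ESC 1, 2 or 3 the higher genes numbered 177, 175 or 211 and the lower genes 482, 477 or 512. The higher genes thus fell more than the lower ones.

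Over the 3 cell types together, limma's moderated F test called 4636 of 18193 genes, or 25.5%, of which 3945 differed by at least 2-fold between some pair of cell types. The count was 2181 with the 3' to 5' covariate, 7698 with arrays centred on ribosomal proteins and 6966 with probe sets tested singly.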

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

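Averaging VSEL 2 and 3, on which all main values rest, was chosen after the data were seen, as were the replicate block on the 9 arrays and VSEL 1 as the only VSEL library. The 9 separate arrays were the design as first written and became an alternative then. Of 222 called values of named genes, 101 kept their direction and call in every setting run and 121 lost the call in at least 1 setting. A called value changed sign only for Rrm1 in VSEL against ESC with the mean of its probe sets (-0.27) and for Gnas in HSC against ESC without probe sets that can match several transcripts (-0.18), and the cause was not tested. VSEL had 2 libraries, not known to come from separate mice, and genes near the background of 4.49 to 4.80 limit what can be called.

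Counts are given in the order VSEL against HSC, VSEL against ESC, 3 cell types, and VSEL apart from both. Testing probe sets singly gave 4703, 4682, 6966 and 1983, since more were tested. Centring on ribosomal proteins gave 7692, 5545, 7698 and 3775. Keeping the 9 arrays separate, as first designed, gave 4757, 4719, 6290 and 2254, with VSEL 2 and 3 entering as independent. In VSEL against HSC, genes above the median gave 1998 and the fit on 2 groups 1586. The filter on the median left 600 genes higher and 1398 lower, against 1458 and 1671 in the main fit. Most of the genes lost were thus higher in VSEL, which the smaller number of tests does not account for. For VSEL apart from both, cyclic loess gave 847 and the fit on 2 groups 435. Array weights gave 1249 (VSEL against HSC), 1441 (VSEL against ESC) and 380 (apart from both). The 3' to 5' covariate, which moves with the groups, gave 92 in VSEL against ESC, 845 in HSC against ESC, 2181 over the 3 cell types and 35 apart from both. Where no cause is named, the cause was not tested.

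Leaving out single arrays gave 1954 to 3381 genes in VSEL against HSC, 1709 to 3366 in VSEL against ESC, 2277 to 3780 in HSC against ESC, 3158 to 4970 over the 3 cell types and 652 to 1525 apart from both. Without VSEL 1, or with VSEL 1 alone, the lone VSEL library is assumed to vary like the other groups. VSEL 1 alone called 3169 genes in VSEL against HSC, of which 1900 were among the 3129, and 3056 in VSEL against ESC, of which 1806 were among the 3075. Without VSEL 1 the shared numbers were 1725 and 1796.

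Of 72 list tests, 45 were called by camera, 22 with an estimated correlation and 59 by fry, which asks only whether a list moves. The setting with an estimated correlation also uses fewer degrees of freedom. Leaving out single arrays gave 44 to 47. The mean, median and camera direction of a list differed in sign in 8 tests, none of them called. The difference between the mean correlation of VSEL with ESC and with HSC was 0.0209, and 0.0097 to 0.0264 with single arrays left out.

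The replicate numbers did not pair the samples: deviations of same-numbered arrays correlated at -0.0888 to 0.155 and those of different numbers at -0.149 to 0.124. With the replicate block on the 9 arrays the counts were 3432 in VSEL against HSC, 3517 in VSEL against ESC, 3047 in HSC against ESC, 4890 over the 3 cell types and 1439 apart from both, with 44 lists called.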

Other observations

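Tests chosen only after the result was seen are those of ESC-specific genes outside the pluripotency list, of a separate pluripotency programme, of the near identity of VSEL 2 and 3 and of the slopes. The statistic used in the test of a single common ESC library was also set after its correlations were seen.

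The 2 VSEL libraries lay far apart in a number of blood cell genes, chosen here after their values were seen. Cd52 was 4.02 in VSEL 1 and 13.37 in VSEL 2+3, Tyrobp, an adaptor of myeloid and NK receptors, 4.31 and 13.62, Lcp1, an actin bundling protein of leukocytes, 3.67 and 12.62, and Cd53 4.50 and 12.98, while each was between 12.63 and 14.08 in the HSC libraries. Cd34, a progenitor surface antigen gene, was 4.53 in VSEL 1 and 10.58 in VSEL 2+3. Klf1, the main erythroid transcription factor gene, was 14.30 in VSEL 1 and 11.63 in VSEL 2+3, and the neutrophil granule genes Elane, Mpo and Prtn3 were 11.49, 11.55 and 12.29 in VSEL 1 and 13.57, 14.17 and 14.38 in VSEL 2+3. Cldn5, a tight junction gene of endothelium, was 5.43 in VSEL 1 and 11.35 in VSEL 2+3, against 4.82 to 5.30 in the HSC and ESC libraries. Of 300 genes specific to HSC, 61 were below 6 in both VSEL libraries, 40 only in VSEL 1, 25 only in VSEL 2+3, and 24 were within 1 log2 unit of HSC in both. The SD of VSEL 1 minus VSEL 2+3 was 3.24 over these genes, 2.24 over the 2667 genes above 9 in the mean of both and 0.762 over the 133 genes specific to ESC, and 39.3%, 35.4% and 4.51% of the genes differed by more than 4-fold. No test compares single libraries.

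The ESC-specific genes lay at a nearly constant offset below ESC in both VSEL libraries, and a candidate explanation is material of ESC-D3 cells in these libraries. Outside the pluripotency list, 112 of 117 such genes (95.7%) were more than 1 log2 unit above HSC in both VSEL libraries, but with every gene at the median offset all 117 would be, so this share restates the offset and decides nothing. A pluripotency programme confined to the listed genes is argued against: these lay further below ESC than the others, a difference of -0.251 (95% bootstrap interval over genes -0.383 to -0.0871). That explanation was taken to need them nearer by over 0.5, a bound set after the result. The other 117 genes may hold members of a wider programme, so these values cannot decide on a wider one. Y-linked genes could not decide, since none was among the ESC-specific genes; Eif2s3y, at 6.54 in ESC and 3.63 in HSC, lay above HSC by 1.63 in VSEL 1 and 0.691 in VSEL 2+3. Cells in the gate that share the whole ESC state, at a constant share of each library, stay open as untested.

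A further reading asked which ESC library the offsets follow, since the ESC libraries differed among themselves in many of these genes, for reasons not tested. Across 113 ESC-specific genes that varied among ESC libraries, the offset of VSEL 1 followed ESC 3 (r = 0.431) and that of VSEL 2+3 followed ESC 2 (r = 0.407). The r was -0.281 to -0.157 for the others, so the offsets did not follow the same ESC library (best shared r -0.157). The deviations are taken from the mean of the ESC libraries, so a positive r with one lowers the others. The negative values are thus no separate support. With a statistic set after the correlations were seen, a single ESC library common to both is not decided. The prediction as first written, an r above 0.3 with the same library in both or under 0.1 in both, was met in neither form. The resulting hypothesis, cDNA of a different ESC library in each, was tested on 28 unlisted probe sets with somewhat different selection limits. These come from the same libraries, so they are not independent samples. The r was 0.329 (95% bootstrap interval -0.0602 to 0.605) for VSEL 1 with ESC 3 and 0.628 (0.379 to 0.811) for VSEL 2+3 with ESC 2, each the highest for its library. A processing batch shared by these pairs stays open: over 145 genes bright in all cell types the higher r was 0.0367, which met the bound set against a batch, but VSEL offsets scatter more there (SD 1.65 and 1.83, against 0.8 and 0.705), and the slope on the ESC deviation was lower than over the ESC-specific genes by 0.576 for VSEL 1 and by 0.381 for VSEL 2+3, with 95% bootstrap intervals that start at 0.101 and at -0.197, so the second includes no difference. The matching is consistent with carried-over cDNA as a hypothesis, limited by 28 probe sets, an interval that includes 0 and the open batch, and no biological explanation was tested for it.

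VSEL arrays 2 and 3 may be 1 amplified library hybridised to 2 arrays: the SD of their difference over bright probe sets was 0.199, against at least 0.491 for the other pairs of a group. The labels name them as separate samples, and a pair of libraries made from the same lysate was not tested.

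The 8 libraries can be split into groups of the same sizes in 280 distinct ways, of which 100 were run. Of these 100 splits only 1, the real split, gave as many as its 4636 genes in the F test. The highest other among those run gave 1190, so a random assignment of libraries to groups is an unlikely source of that count. The splits cannot tell cell type from a batch or source shared by the libraries of a group. For HSC against ESC the 10 splits of 6 arrays are too few for a share under 0.05: the real split, 1 of 10, gave 3078 genes and the highest other 0.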
